A study of Mus musculus with 8 samples.

How the data were processed

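RNA was measured in outer medullary collecting ducts of C57BL/6J mice fed a normal-salt (0.3%) or a high-salt (3%) diet for 3 days. Per the labels' protocols, ducts were dissected from enzyme-digested kidneys, 100 to 120 tubules of 1 mouse were pooled for each library, and libraries were made with a stranded mRNA kit. The 8 libraries fall into 4 per diet, and each stands for 1 mouse.

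Per the submitters' processing notes, FastQC and Trimmomatic were used and the genome build was mm10. The aligner, the counting program, the strand setting and the gene annotation are not given in the sources used here. The authors deposited a table of CPM (counts scaled to a common library total) and a table of TPM (the same with transcript length taken into account), each with 55291 gene symbols and 1 column per library. The values deposited as CPM were on a log2 scale and shared a floor of -5.29 in all libraries. Less 2 to the power of that floor, 2 to the power of each value summed to 1 M per library. The deposited TPM values summed to between 999838 and 999898 per library and were rounded to 3 decimals. No scaling factor between libraries was found in the CPM values.

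The column names gave the diet of each library but carried the numbers 1, 2, 3 and 6 for normal salt and 2, 3, 4 and 6 for high salt, whereas the sample titles are numbered 1 to 4. Libraries are therefore named by diet and column number, and no column was tied to a single sample title.

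The planned test assumed linear CPM, so 2 was raised to the power of each deposited value. Then 2 to the power of the floor was subtracted and each library was scaled to 1 M. The CPM steps within a library gave estimated counts that were all multiples of 0.01 (tolerance 0.05 of a step), of which 84.7% to 85.9% were whole within 0.005 counts. Because these were estimated counts and not whole reads, a count model was not used as the main test. Recovered totals ranged from 64.8 to 94.1 M estimated counts per library, so that 1 count was worth 0.0106 to 0.0154 CPM. The highest correlation across genes between any 2 libraries was 0.997.

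Genes with a CPM of at least 1 in at least 4 of the 8 libraries were kept, which left 13401 genes. High salt was compared with normal salt on log2(CPM + 1) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean-variance trend, a two-sided test and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. Errors beside means are standard deviations over the 4 libraries of a diet.

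Gene lists were fixed before the data were examined. They covered principal and intercalated cells, transport, hormone and tonicity responses, general cell programmes and markers of other cell types. The lists with at least 5 tested members, 37 in all, were compared with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Lymphocyte and erythrocyte markers had 2 tested members each and were left out. The mean log2(CPM + 1) of each list per library was compared by an exact two-sided permutation test over all 70 assignments of 4 and 4 libraries, whose smallest possible p is 0.0286. Members of a list were also counted as adjusted over the list alone.

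The genes named were set by a rule fixed before the data were examined. It took up to 12 called genes per direction with a mean of at least 5 CPM in the higher group and no overlap between the diets. Where fewer than 5 passed in a direction, it took the 8 with the smallest unadjusted p and stated that some did not pass. It added up to 4 members of each list that was called or held a called gene, up to 2 members of other lists, and 16 genes of collecting duct physiology whatever their result. Predicted genes and pseudogenes were left out of the first part of the rule. Any gene named outside the rule is said to be so.

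The gene test was tested on simulated data for this comparison, drawn for the real genes from their means and library sizes, with 200 changed genes in each of 5 runs and 13435 genes tested on average. It recovered 45.3% of 1.5-fold changes, 88.4% of 2-fold, 98.4% of 3-fold and 99.2% of 4-fold changes, with the right direction in 100% of calls, and 4.98% of calls were false. In 10 runs without any changed gene the highest number of calls was 2. A list shifted 1.5-fold was called in 5 of 5 runs. The simulated genes were drawn independently of each other, so this test does not cover the correlation between members of a list. It also held 200 changed genes and no library that stood apart, so the recovered shares need not hold for the real comparison.

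Gene positions and the length of the longest transcript came from GENCODE M21 on mm10, matched by symbol, and 53292 of the symbols (96.4%) were found there. Alternatives planned before the data were examined covered the pseudocount, the filter, scaling, TPM, robust moderation, array quality weights, gene list tests and leaving out each library in turn. Others were added afterwards: limma's voom on the estimated counts, the deposited log2 CPM unchanged, a covariate for thick ascending limb markers, removal of the trend with transcript length in each library (loess, span 0.3), a block for shared column numbers, and leaving out normal-salt library 1 with high-salt library 6. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.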

Results

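The outer medullary collecting duct carries urine through the outer medulla of the kidney. It holds principal cells, which take up sodium and water, and intercalated cells, which move acid and base. RNA was sequenced from ducts dissected from C57BL/6J mice, an inbred laboratory strain, after 3 days on a normal-salt (0.3%) or a high-salt (3%) diet. Each diet had 4 libraries, and each library was a pool of 100 to 120 tubules from 1 mouse. Recovered totals averaged 80.8 ± 12.4 M estimated counts under normal salt and 76.5 ± 7.93 M under high salt (SD, n = 4 each). Levels are given in CPM, counts scaled to a common library total, and members of a gene list are counted as higher or lower by their mean log2(CPM + 1). Libraries are named by diet and column number, and the labels do not say that a shared number pairs mice across diets.

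The comparison addressed which transcripts of this segment differ between normal and high salt intake. Scnn1a, the alpha subunit of the epithelial sodium channel, fell from 1198 ± 135 CPM under normal salt to 485 ± 125 CPM under high salt (SD, n = 4 each). Its log2 fold change was -1.33 (SE 0.17, adjusted p = 0.026). Id1, an inhibitor of helix-loop-helix transcription factors, fell from 84.2 ± 7.73 to 20.8 ± 9.31 CPM (log2 fold change -2.06, SE 0.25, adjusted p = 0.0201), and its relative Id2 fell from 241 ± 28.1 to 124 ± 11.3 CPM (-0.95, SE 0.10, adjusted p = 0.0201). Trpv6, an epithelial calcium channel, rose from 29.4 ± 5.22 to 96.8 ± 37.7 CPM (1.63, SE 0.23, adjusted p = 0.0336). Slc4a4, a sodium bicarbonate cotransporter, rose from 31.4 ± 5.49 to 84.8 ± 25.5 CPM (1.37, SE 0.19, adjusted p = 0.0336).

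The other genes that rose were Emilin2, an extracellular matrix glycoprotein, from 25.5 ± 6.30 to 78.0 ± 22.3 CPM, and Arhgdig, from 5.71 ± 1.49 to 14.6 ± 1.53 CPM. Kcnn3, a calcium-activated potassium channel, fell from 23.1 ± 4.56 to 7.96 ± 1.67 CPM (log2 fold change -1.43, SE 0.17). Defb1, the antimicrobial peptide beta-defensin 1, fell from 845 ± 109 to 440 ± 63.7 CPM (-0.94, SE 0.13), and Pbld1 fell from 39.3 ± 1.83 to 19.7 ± 2.69 CPM (-0.96, SE 0.11). Angpt4, an angiopoietin, lies below the level set for naming genes and was added after its values were seen. It fell from 3.62 ± 1.40 to 0.321 ± 0.142 CPM. In all 11 genes the 4 high-salt libraries did not overlap the 4 normal-salt libraries.

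**Figure D1:**
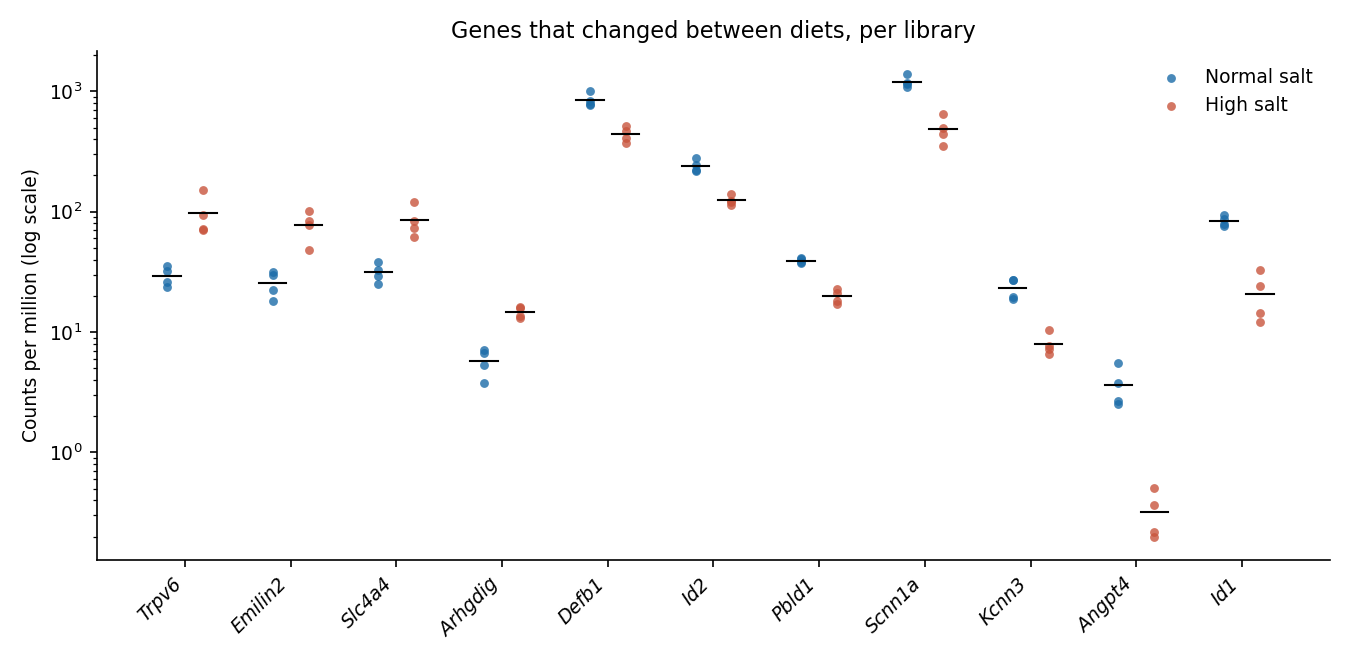
Level of the 11 genes that changed between diets, with 1 point per library (normal salt in blue, high salt in red, n = 4 each), a black bar at the mean and a log axis in CPM. The diets do not overlap in any of the genes, which are ordered from the highest log2 fold change (Trpv6, 1.63) to the lowest (Id1, -2.06).

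Of 13401 genes tested with limma, 11 changed at an adjusted p under 0.05, with 4 higher and 7 lower under high salt. At an adjusted p under 0.1 there were 79, with 52 higher and 27 lower. An unadjusted p under 0.05 was reached by 1383 genes (798 higher, 585 lower), where chance gives 670. The diets did not overlap in 858 genes (6.40%), against 2.86% by chance. Genes of the same libraries are not independent, and how far these numbers vary by chance was not tested. The excess alone therefore does not show an effect of the diet. The count depended on single libraries: limma called 0 genes without normal-salt library 3 or high-salt library 4 (1231 and 924 at an unadjusted p under 0.05), 1 without normal-salt library 6 (not among the 11) or high-salt library 3, 5 without high-salt library 2, and 50, all 11 among them, without normal-salt library 1. All 11 had the same direction in each of these fits, which their lack of overlap between the diets fixed in advance. Without a filter on low values limma called 0 of 30343 genes (1933 at an unadjusted p under 0.05), where voom on the filtered genes called 10.

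In GENCODE M21 on mm10, the symbols of all 11 genes match protein-coding genes. Scnn1a lies on the plus strand of chromosome 6 from 125320659 to 125344943, and Trpv6 on the minus strand of chromosome 6 from 41620624 to 41636405. Id1 lies on chromosome 2 from 152736251 to 152737410 and Id2 on chromosome 12 from 25093799 to 25097140. Slc4a4 spans 88886818 to 89239653 on chromosome 5, and Kcnn3 spans 89520164 to 89675132 on chromosome 3. The values are per gene and do not separate exons or isoforms.

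The genes with higher means under high salt, at least 5 CPM there and the next smallest p included 4 that the rule named and that did not pass, each with an adjusted p of 0.0529. Phlda1, which responds to growth factor signalling, had 55.2 ± 2.72 and 105 ± 20.3 CPM, and Il17rd, an inhibitor of fibroblast growth factor signalling, had 2.55 ± 0.758 and 8.60 ± 2.53 CPM. Lig1, the DNA ligase of replication, had 23.3 ± 0.616 and 40.0 ± 6.84 CPM. Ugt1a1 had 1.39 ± 0.998 and 6.67 ± 1.49 CPM, but it shares exons with other Ugt1a genes, so its reads may belong to any of them.

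Principal cell genes went both ways. Of 20 members tested, 1 passed over all genes (Scnn1a, lower), and adjusted over the list alone 4 were higher and 2 were lower. Aqp2, the vasopressin-regulated water channel, was measured at 9979 ± 2120 and 15689 ± 1618 CPM under normal and high salt (log2 fold change 0.67, adjusted p = 0.286), and Aqp3, the basolateral water channel, at 2688 ± 382 and 4328 ± 729 CPM (0.68, adjusted p = 0.162). Kcnj1, the potassium channel ROMK, had a log2 fold change of 0.61 (adjusted p = 0.0937), and Stc1, the hormone stanniocalcin 1, of 1.87 (adjusted p = 0.107). The beta subunit Scnn1b had -0.49 (adjusted p = 0.281) and the gamma subunit Scnn1g -0.19 (adjusted p = 0.678). The list mean was 9.49 ± 0.02 under normal salt and 9.58 ± 0.03 under high salt on the log2(CPM + 1) scale, with an exact permutation p of 0.0286, the smallest the design allows, and 0.529 after adjustment over 37 lists. The camera test gave an adjusted p of 0.97.

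Of 28 sodium and chloride transport genes, Slc4a4 rose and Scnn1a fell over all genes, and adjusted over the list alone 2 were higher and 4 were lower. Bsnd was measured at 119 ± 18.2 and 88.4 ± 11.2 CPM (log2 fold change -0.43, adjusted p = 0.223). It is also known from the thick ascending limb, whose markers had a mean of 5.08 ± 0.55 under normal salt and 4.13 ± 1.34 under high salt. Of 12 potassium transport genes 0 passed limma's test over all genes and 2, Kcnj1 and Atp12a, adjusted over the list alone.

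Targets of aldosterone and glucocorticoids had lower means in 15 of 22 tested members. Scnn1a was the 1 member that passed over all genes, and adjusted over the list alone 2 were lower (Scnn1a and Sgk1) and 1 was higher (Kcnj1). Sgk1, a kinase that raises sodium channel activity, was measured at 360 ± 172 and 111 ± 35.9 CPM (log2 fold change -1.59, SE 0.35, adjusted p = 0.124). Zbtb16, a transcription factor induced by glucocorticoids, had 39.3 ± 21.8 and 14.4 ± 11.3 CPM (adjusted p = 0.405). Hsd11b2, which inactivates glucocorticoids in these cells, had 4067 ± 307 and 3947 ± 204 CPM (-0.04, adjusted p = 0.942). The list mean was 7.60 ± 0.08 and 7.33 ± 0.15 (exact permutation p = 0.0571), and camera gave an adjusted p of 0.0687. Camera called this list as lower without normal-salt library 1 (adjusted p = 0.023), high-salt library 4 (0.015) or high-salt library 6 (0.0259), within a range of 0.015 to 0.171 over the 8 libraries left out in turn.

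Intercalated cell genes were lower as a list by camera (adjusted p = 0.0132). With an estimated correlation, which was -0.0187 for this list, camera did not call it (p = 0.0118, adjusted p = 0.438). Limma's fry, which tests whether a list's genes move one way on balance, gave an adjusted p of 0.0221. Of 26 members 17 had lower means, 0 passed limma's test over all genes (8 lower and 2 higher at an unadjusted p under 0.05), and adjusted over the list alone 6 were lower and 2 higher. Among the lower members were Rhcg, an ammonia channel, at 1934 ± 226 and 1307 ± 85.7 CPM (log2 fold change -0.56, adjusted p = 0.109), and Atp6v1b1, the proton pump subunit of these cells, at 896 ± 70.2 and 677 ± 37.3 CPM (-0.40, adjusted p = 0.159). Members that went the other way were Car15, a carbonic anhydrase, at 40.1 ± 41.4 and 332 ± 209 CPM (3.19, SE 0.59, adjusted p = 0.0815), and Atp12a, the colonic proton-potassium pump, at 10.7 ± 5.73 and 24.7 ± 5.94 CPM (1.21, adjusted p = 0.155). Slc4a1, the chloride-bicarbonate exchanger of acid-secreting intercalated cells, had 2709 ± 525 and 2722 ± 443 CPM (0.01, adjusted p = 0.99). The mean of the list was 7.82 ± 0.11 and 7.76 ± 0.17 (exact permutation p = 0.571). The members had a mean log2 fold change of -0.07 and a median of -0.15. The mean turned to 0.0393 with the thick ascending limb marker mean as a covariate and to 0.000980 without high-salt library 3. Camera still called the list in these fits (adjusted p = 0.00531 and 0.0306). Its adjusted p by camera was 0.00598 to 0.0497 over the 8 libraries left out in turn.

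Cell cycle genes were higher under high salt as a list by camera (adjusted p = 1.53e-19), but not with an estimated correlation (adjusted p = 0.863 with an estimated correlation). Of 34 members 32 had higher means, with a median log2 fold change of 0.81. Over all genes 0 passed limma's test (25 had an unadjusted p under 0.05, all higher), and adjusted over the list alone 17 were higher. Mki67, a marker of dividing cells, was measured at 8.77 ± 6.08 and 29.6 ± 8.48 CPM (1.80, SE 0.37, adjusted p = 0.0937), and Cenpf, a kinetochore protein, at 3.15 ± 1.20 and 8.61 ± 1.73 CPM (1.23, adjusted p = 0.0792). Kif11, a spindle motor, had a log2 fold change of 1.29 (adjusted p = 0.0815) and the checkpoint kinase Bub1 of 1.21 (adjusted p = 0.0937). The list mean was 2.65 ± 0.51 and 3.49 ± 0.27 (exact permutation p = 0.0857), and normal-salt library 1 had 3.37, the highest of its diet and the highest of the 4 in fibroblast markers (4.24). Without that library 9 members passed over all genes, 30 adjusted over the list alone, and the exact permutation p was 0.0286, the smallest that 3 and 4 libraries allow. Only that library of its diet lay above the lowest high-salt value (3.22), so leaving it out fixed this p in advance. In the same fit fibroblast and pericyte markers were higher too (mean log2 fold change 0.51, exact permutation p = 0.0857).

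Cholesterol synthesis genes were higher as a list by camera (adjusted p = 0.000307), but not with an estimated correlation (adjusted p = 0.874 with an estimated correlation). Means were higher in 21 of 24 members, with a median log2 fold change of 0.33. By limma 0 members passed over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. Among these were Stard4, a sterol carrier (log2 fold change 0.42, adjusted p = 0.429), and Fdps, which makes farnesyl diphosphate (0.56, adjusted p = 0.443). The list mean was 5.26 ± 0.25 and 5.58 ± 0.41 (exact permutation p = 0.229). The camera call was lost without high-salt library 6 (adjusted p = 0.057; over the alternatives 1.92e-14 to 0.874).

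Markers of the thick ascending limb, the neighbouring segment, were lower as a list by camera (adjusted p = 0.000781), but not with an estimated correlation (adjusted p = 0.874 with an estimated correlation). All 13 tested members had a lower mean log2(CPM + 1), although Irx1, named after its values were seen, had 5.58 ± 1.90 and 6.38 ± 7.97 CPM. By member, 0 passed limma's test over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Umod, the uromodulin of that segment, was measured at 781 ± 444 and 506 ± 799 CPM, and Slc12a1, its sodium-potassium-chloride cotransporter, at 263 ± 103 and 182 ± 258 CPM. The marker mean was 3.06, 3.28 and 4.19 in high-salt libraries 2, 3 and 4 and 6.01 in high-salt library 6 (exact permutation p = 0.286 over all 8 libraries). The camera call was lost without high-salt library 2 (adjusted p = 0.0541; over the alternatives 3.99e-15 to 0.874).

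**Figure D2:**
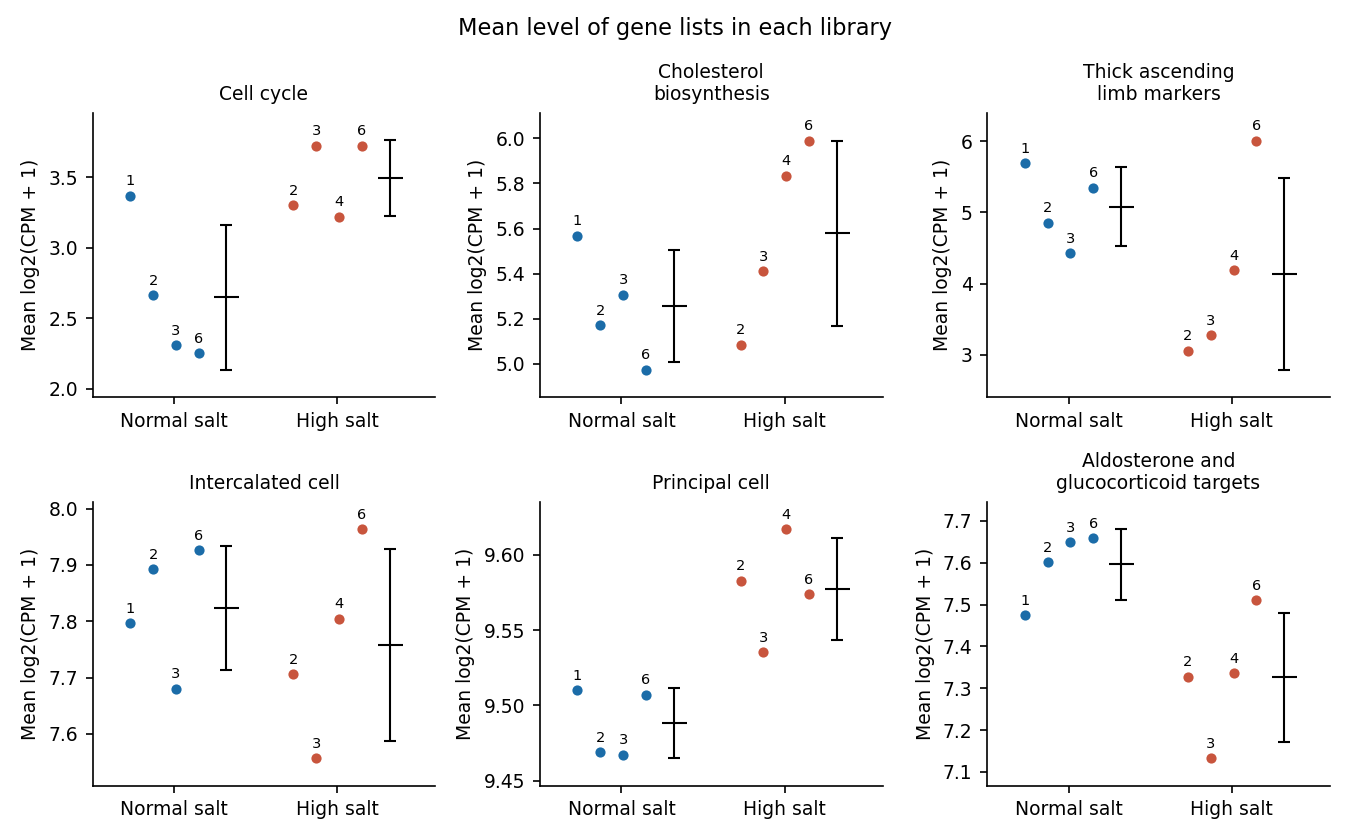
Mean log2(CPM + 1) of 6 gene lists in each library, with points numbered as the libraries (normal salt in blue, high salt in red) and a black bar with whiskers at the mean ± SD of the 4 libraries of a diet. Each panel has its own vertical axis, which does not start at 0; the cell cycle list of normal-salt library 1 (3.37) and the thick ascending limb markers of high-salt library 6 (6.01) are the highest of their diet.

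Markers of other cell types were compared in 9 lists with exact permutation tests, and in 0 of them was p under 0.05, where the smallest possible p is 0.0286. By camera 1 of the 9, the thick ascending limb, was called. Distal convoluted and connecting tubule markers had higher means in 8 of 10 members (camera adjusted p = 0.0552), and adjusted over the list alone 3 were higher: Emx1 (log2 fold change 0.82), the sodium-calcium exchanger Slc8a1 (0.52) and the calcium channel Trpv5 at 1.79 ± 1.80 and 4.73 ± 1.36 CPM, which was named after its values were seen. Trpv6, which rose, is also known from those segments. Fibroblast and pericyte markers had means of 3.18 ± 0.72 and 3.33 ± 0.35 (exact permutation p = 0.771), and macrophage markers 2.26 ± 0.65 and 2.01 ± 0.32 (p = 0.657, exact permutation). Of 11 macrophage markers 9 had lower means, but Ptprc was higher adjusted over the list alone, at 9.42 ± 1.06 and 14.1 ± 2.18 CPM. The exact permutation p was 0.571 for endothelium, 0.857 for thin limb, 0.6 for proximal tubule, 0.971 for inner medullary duct and urothelium, and 0.743 for podocytes.

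Genes of vasopressin and cyclic AMP signalling were not called as a list (24 tested, camera adjusted p = 0.556), and adjusted over the list alone 2 were higher, Crem (log2 fold change 0.99) and Aqp3. The vasopressin receptor Avpr2 had 655 ± 109 and 655 ± 49.1 CPM (adjusted p = 0.982). Targets of the tonicity factor Nfat5 had a camera adjusted p of 0.6, a median log2 fold change of 0.03 and a mean of -0.03. Adjusted over the list alone, the betaine transporter Slc6a12 was higher (1.27) and Sgk1 was lower, and Nfat5 itself had a log2 fold change of -0.09 (adjusted p = 0.929). In the list of endothelin, nitric oxide, prostaglandin and purinergic signalling (camera adjusted p = 0.6), 1 of 29 members was higher adjusted over the list alone. It was Ren1, renin, at 0.353 ± 0.250 and 2.96 ± 1.28 CPM (adjusted p = 0.0529 over all genes). Edn1, endothelin 1, had 3.40 ± 1.02 and 5.50 ± 2.88 CPM (adjusted p = 0.631) and its receptor Ednrb 92.2 ± 4.93 and 88.7 ± 10.8 CPM (adjusted p = 0.878). Nos1, neuronal nitric oxide synthase, was below the level tested, at 0.0883 ± 0.161 and 0.0217 ± 0.0434 CPM.

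Genes of the unfolded protein and integrated stress responses had means of 6.24 ± 0.05 and 6.36 ± 0.04 (exact permutation p = 0.0286, the smallest the design allows, and 0.529 after adjustment over 37 lists). Camera gave an adjusted p of 0.0957, and by limma 0 of 27 members passed over all genes or adjusted over the list alone, while 5 were higher at an unadjusted p under 0.05. Among these were Psat1, an enzyme of serine synthesis (log2 fold change 0.69), and the transcription factor Xbp1 (0.49). Gdf15, a stress-induced hormone, had 259 ± 94.8 and 397 ± 170 CPM (adjusted p = 0.596). Of 30 hypoxia and glycolysis genes, adjusted over the list alone 2 were higher, Egln3 (1.01) and Ndrg1 (0.48), and 2 were lower, Bnip3 (-0.43) and Pfkl (-0.29), both named after their values were seen, with a camera adjusted p of 0.836. Among 16 tubule injury genes, adjusted over the list alone 2 were higher and 2 lower (camera adjusted p = 0.872). Lcn2, a marker of tubule injury, was measured at 66.8 ± 8.18 and 39.2 ± 7.87 CPM (-0.77, adjusted p = 0.0815), and Krt19 had a log2 fold change of 0.85.

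The remaining lists were not called by camera. Adjusted p was 0.0747 for mitochondrial transcripts, 0.0799 for proton pump subunits, 0.0861 for endothelial markers, 0.253 for antigen presentation and for thin limb markers, 0.404 for p53 and apoptosis, 0.415 for eicosanoid metabolism, and 0.556 for potassium transport, macrophage markers and proximal tubule markers. It was 0.6 for immediate early genes, 0.604 for inflammation and for fatty acid oxidation, 0.659 for the circadian clock, 0.717 for ribosomal proteins, 0.737 for interferon response and fibroblast markers, and 0.812 for podocyte markers. For heat shock and oxidative stress genes it was 0.836, for oxidative phosphorylation 0.872, for extracellular matrix 0.899, for inner medullary duct and urothelium markers 0.604, and for sodium and chloride transport 0.253.

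The deviation of normal-salt library 1 from the other libraries of its diet fell along transcript length. Its Spearman correlation was -0.57 across 13193 genes, which are not independent replicates. The correlation was -0.0846 to 0.114 in the high-salt libraries and 0.189 to 0.451 in the other normal-salt libraries. Those normal-salt libraries were compared with means that include library 1, so their values in part mirror it. Mitochondrial transcripts made up 8.55% of the counts of normal-salt library 1, against 5.77% to 6.49% in the others. Its fibroblast and macrophage marker means were 4.24 and 3.23, the highest of the 8. Limma's array weight for it was 0.239, the lowest of the 8, and the next lowest was 0.741.

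**Figure D3:**
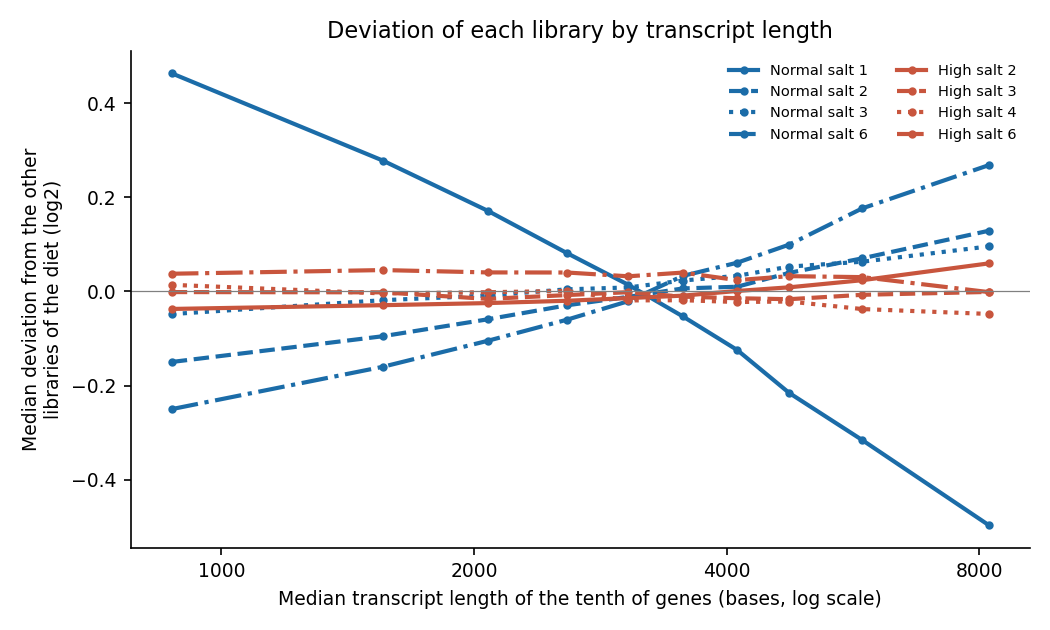
Median log2 deviation of each library from the mean of the other libraries of its diet (vertical axis) for genes split into 10 parts by length of the longest transcript (horizontal axis, bases, log scale), with normal salt in blue and high salt in red and 1 line per library. Normal-salt library 1 falls from 0.46 in the shortest part to -0.50 in the longest. The lines of the other normal-salt libraries in part mirror it, as the means they are compared with include it.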

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

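The test of fibroblast and macrophage markers in normal-salt library 1 was chosen only after the result was seen.

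Of 282 named values and list means per diet that were tested for a single library far from the other 3, 6 stood apart (2.13%), where chance gives about 5%. On the log2(CPM + 1) scale, Phlda1 was 6.25 in high-salt library 6 against 6.82 to 6.91 in the other 3 high-salt libraries. Car15 was 6.69 in normal-salt library 2 against 4.23 to 4.43. Akr1b3, aldose reductase, was 6.15 in normal-salt library 6 against 7.03 to 7.09. Acaa2, an enzyme of fatty acid oxidation, was 7.91 in normal-salt library 1 against 7.60 to 7.64. Ndrg1 was 9.77 in normal-salt library 1 against 10.05 to 10.10, and the mean of vasopressin and cyclic AMP signalling genes was 5.97 there against 6.37 to 6.42.

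Of the 6 values, 3 came from normal-salt library 1, in which 488 genes were more than 2-fold off the other libraries of its diet, against 102 to 259 in the other 7 libraries. Its deviation across genes had a Spearman correlation of -0.570 with transcript length and of 0.0885 with GC content, so a bias against long transcripts in that library, as shortened RNA could leave, stays open. Fibroblasts and immune cells carried along with its tubules stay open too: its fibroblast and pericyte marker mean lay 0.549 above the next highest library and its macrophage marker mean 0.861 above (log2), with Col1a2 at 139 CPM there against 16.6 to 81.7 and Vim at 108 CPM against 14.8 to 66.0 in the other 7. Of these 2 markers, Col1a2 is also in the extracellular matrix list and Vim in the tubule injury list. The design puts no treatment on a single library, so no biological explanation was tested.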

How the results depend on the processing

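The following alternatives were added after the data were seen: the block for column numbers and the same 6 libraries without it, the deposited log2 values, voom, the thick ascending limb covariate, removal of the length trend, and leaving out normal-salt library 1 with high-salt library 6. The edgeR and DESeq2 fits, planned only for whole reads, were not run, since the steps gave estimated counts. The block planned on the title numbers was not run because the columns carry other numbers.

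The 11 called genes kept their direction in each of the 24 alternatives that tested them. As the diets did not overlap in these genes, leaving out libraries or changing the pseudocount could not turn it. Against 11 calls (4 higher, 7 lower), quantile normalization gave 9 (2 higher, 7 lower), log2(TPM + 1) gave 5 (0 higher, 5 lower, with 1229 at an unadjusted p under 0.05), robust moderation gave 22 (11 higher, 11 lower) and array quality weights gave 129 (88 higher, 41 lower, all 11 among them). Without a filter on low values limma called 0 (0 higher, 0 lower, with 1933 at an unadjusted p under 0.05), with 30343 genes tested. The covariate gave 39 (30 higher, 9 lower), removal of the length trend 25 (12 higher, 13 lower, all 11 among them), and leaving out normal-salt library 1 with high-salt library 6 gave 43 (26 higher, 17 lower). Leaving out 1 library at a time gave 0 to 50 calls, with 0 to 36 higher and 0 to 14 lower. The 0 came without normal-salt library 3 or high-salt library 4 (1231 and 924 at an unadjusted p under 0.05) and the 50 without normal-salt library 1. For these changes in count, the cause was not tested.

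Column numbers 2, 3 and 6 occur in both diets. Libraries with the same number had correlations of their deviations of 0.208, 0.287 and 0.002. Those with different numbers had -0.275 to 0.296, so these values do not show whether the numbers pair libraries. With the numbers as a replicate block over 6 libraries, 37 genes were called (22 higher, 15 lower) and 12 lists, and without the block the same 6 libraries gave 23 genes (15 higher, 8 lower). With the replicate block over these 6 libraries, mean differences that turned sign were -0.44 for thin limb, 0.0343 for macrophage, -0.36 for inner medullary duct and -0.0205 for podocyte markers. A block that holds 1 library of each diet leaves the mean difference as it is, so these signs come from the 2 libraries left out.

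Against 4 called lists, an estimated correlation left 0 (1 list at an unadjusted p under 0.05) and fry, which tests whether a list's genes move one way on balance, left 1, intercalated cells. Leaving out normal-salt library 1 with high-salt library 6 gave 11, and leaving out 1 library at a time gave 4 to 10, with 10 without normal-salt library 1, normal-salt library 6 or high-salt library 4. Among those that gained a camera call were distal convoluted and connecting tubule markers without normal-salt library 2 or 6 or high-salt library 2 or 4 (adjusted p 0.00632 to 0.28 over the 8 left out in turn), which all 8 libraries also gave under median-ratio scaling (0.0485) and with the covariate (0.00269), and mitochondrial transcripts without normal-salt library 2 or 6 or high-salt library 4 (0.0129 to 0.723). Proton pump subunits gained one without normal-salt library 6 or high-salt library 4 (0.00271 to 0.312), endothelial markers without normal-salt library 1 or high-salt library 4 (0.00037 to 0.657), and unfolded protein genes without high-salt library 3 (0.0495 to 0.299). Of the 9 marker lists 0 to 1 had an exact permutation p under 0.05 when 1 library was left out. The 1 was the thick ascending limb without high-salt library 6 (exact permutation p = 0.0286, the smallest that 3 and 4 libraries allow). Only that library of its diet lay above the lowest normal-salt value (6.01 against 4.43), so leaving it out fixed this p in advance. The causes were not tested.

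Of 2414 values of 101 named genes under the alternatives, 2250 kept direction and side of the threshold, 83 fell below it, 62 passed it and 19 changed sign. The sign changes were in 4 genes near 0, none of them called. Slc4a1 (0.01) was -0.10 with array weights, -0.13 in the 6 libraries with and without the block, -0.21 with the covariate and -0.0204 without the length trend, and -0.11 to 0.14 leaving out 1 library, with the same direction in 14 of 24 alternatives. Hsd11b2 (-0.04) was 0.0011 with array weights, 0.0319 in the 6 libraries with and without the block, 0.0137 without the 2 libraries, and -0.0763 to 0.00899 leaving out 1. Avpr2 (0.01) ranged from -0.0651 to 0.12 and Nfat5 (-0.09) from -0.37 to 0.0550 leaving out 1.

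Among lists, the intercalated cell mean (-0.07) was 0.0393 with the covariate and -0.13 to 0.000980 leaving out 1 library. Camera still called that list with the covariate (adjusted p = 0.00531) and with any 1 library left out (0.00598 to 0.0497). The mitochondrial transcript mean (-0.13) was 0.00577 without the 2 libraries. Thin limb markers (0.05) were -0.0827 with a pseudocount of 0.1. Leaving out 1 library, mean differences ranged from -0.21 to 0.28 for thin limb, -0.41 to 0.0676 for macrophage, -0.10 to 0.56 for proximal tubule, -0.20 to 0.22 for inner medullary duct, -0.0222 to 0.51 for fibroblast and -5.84e-05 to 0.16 for podocyte markers. The causes were not tested.

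Scnn1a ranged from -1.48 to -1.11 over the alternatives and passed in 18 of 24 (adjusted p 0.00357 to 0.228), and Trpv6 ranged from 1.30 to 1.76 and passed in 17 of 24 (0.0133 to 0.228). At these depths 1 count was worth at most 0.0154 CPM, and genes under 1 CPM in more than 4 of the 8 libraries were not tested.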

Other observations

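The splits of the libraries for the gene count, the removal of the length trend, the covariates for thick ascending limb and fibroblast markers, and the correlation among thick ascending limb markers were tests chosen only after the results were seen.

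Without normal-salt library 1, limma called 50 genes, 36 higher and 14 lower under high salt, and the genes named here were chosen after their values were seen. Higher in that fit were Kntc1, a kinetochore protein (log2 fold change 2.02, adjusted p = 0.0144), Cdk1, the kinase that starts mitosis (1.86, adjusted p = 0.0144), and E2f1, a transcription factor of the S phase (2.23, adjusted p = 0.0362). Thymidine kinase Tk1 was higher too (1.68, adjusted p = 0.0362). With all 8 libraries the values were 1.71, 1.49, 1.96 and 1.20, with adjusted p of 0.0815, 0.141, 0.0815 and 0.36. Normal-salt library 1 had the highest cell cycle list mean of its diet (3.37, against 2.25 to 2.66). Leaving it out therefore favoured calls of cell cycle genes in advance. Fibroblast and pericyte markers had a mean log2 fold change of 0.51 without normal-salt library 1 (exact permutation p = 0.0857). With all 8 libraries it was 0.15 (exact permutation p = 0.771). Lower in that fit were Id3, a relative of Id1 and Id2 (-0.77, adjusted p = 0.0477), and Cav2, a caveolin (-0.52, adjusted p = 0.0362). With all 8 libraries they had -0.80 and -0.55, each with an adjusted p of 0.0529.

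The 11 genes that changed were set against 3 explanations. Of 35 splits of the libraries into 4 and 4, 1, the real one, gave as many called genes. The highest of the others gave 1. A share of 1 in 35 is the smallest these splits can give. Mixed splits also carry any diet difference in their spread, and the test was chosen after the calls were seen, so chance is not excluded. Thick ascending limb tubules carried along could differ between libraries, since the markers had a mean pairwise correlation of 0.828 after the diet means were removed, but with their mean as a covariate the log2 fold changes had a median ratio of 0.973 to those without it (lowest 0.815). Of the 11 genes 10 still passed, and Arhgdig went from 1.24 (SE 0.18) to 1.15 (SE 0.20, adjusted p = 0.0523), as its error grew and its fold change shrank. With the length trend removed the median ratio was 0.988 (lowest 0.947) and all 11 passed, so neither accounts for the whole pattern, and an effect of the diet stays a hypothesis.

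Of the same 35 splits, 33 gave at least the 4 called lists of the real one, and the highest of the others gave 17, so chance is not excluded for the number of lists and the libraries differ in ways other than diet. For cell cycle genes, 94.1% of members had a higher mean log2(CPM + 1), which argues against a few members carrying the list. Fibroblasts carried along may add cell cycle transcripts. With their marker mean as a covariate the difference went from 0.84 (SE 0.29) to 0.74 (SE 0.0954), a ratio of 0.875. Fibroblast markers differed little between diets (means of 3.18 and 3.33), so this covariate could take away little. The smaller SE shows that the cell cycle mean varied with these markers within diets. Immune cells were not tested, so cells carried along stay open. More DNA replication was tested on 34 replication genes outside the list. Of these, 32 had a higher mean log2(CPM + 1) and 22 an unadjusted p under 0.05. The exact permutation p of their mean was 0.0571. Camera gave a p of 1.99e-15, and of 0.0709 with an estimated correlation. The bound of 0.05 for the permutation test was set too strictly, since a p above it does not show that means are equal. More replication and the spread between libraries therefore cannot be told apart.

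The lower Id1, Id2 and Id3 gave the hypothesis of lower BMP signalling, the pathway that induces them. Of 12 other genes of that pathway 6 had a higher and 6 a lower mean log2(CPM + 1), with a camera p of 0.484, and Smad6 and Smad7 had log2 fold changes of -0.20 and -0.22. Grem1, a BMP antagonist and the 1 member with an unadjusted p under 0.05, had 1.04 (adjusted p = 0.452). The bound set for this test was a p of 0.05 or more, but such a p leaves a small change open and members that go both ways decide nothing, so lower BMP signalling may or may not be present.

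The higher means of Phlda1 and Il17rd gave the hypothesis of higher ERK signalling. Of 14 feedback targets of ERK 11 had a higher mean log2(CPM + 1), among them Dusp6 (log2 fold change 0.63, adjusted p = 0.163), with a camera p of 0.0158. With an estimated correlation the p was 0.359, and the exact permutation p of the mean was 0.343, so higher ERK signalling and correlated variation between libraries cannot be told apart.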
